A study of Homo sapiens with 18 samples.

How the data were processed

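RNA was sequenced from peripheral blood mononuclear cells (PBMCs) of 3 donors, called A, B and C here, after pre-treatment with indoleacrylic acid (IA) or its solvent dimethyl sulfoxide (DMSO) and stimulation with lipopolysaccharide (LPS). Per the labels' protocols, RNA was extracted on a column kit with a genomic DNA filter, eluted in 30 µL, and 20 ng was turned into libraries by a modified Smart-seq2 protocol, which copies full-length polyadenylated RNA with a template switch and amplifies it by PCR. The 18 deposited tables hold whole-number read counts per gene, 1 table per library, not normalised and not pooled. The submitters' processing notes name TopHat, Bowtie, BWA, HTSeq and edgeR, with no role, order or version, and the genome builds hg19 and GRCh37. The strand setting and the annotation release are not given in the sources used here, so antisense and overlapping genes cannot be told apart, and paralogs that share reads, such as the metallothioneins, CCL4 and CCL4L1, HBA1 and HBA2, HSPA1A and HSPA1B, and FTL and its pseudogene FTLP2, are uncertain. The reference at hand was of another build, so no coordinates are printed, and gene symbols are those of the deposited tables. Symbols since replaced include IL8 (now CXCL8) and C19orf59 (now MCEMP1).

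Each deposited table of counts had 49915 gene features and 5 tallies that name no gene. Of the features, 418 (XIST, its antisense gene and genes of the Y chromosome) were removed for privacy, and 49497 were used. Of these, 26575 matched a symbol or a unique synonym. The tallies stayed out of library sizes and tests. In the 16 libraries that were kept, reads outside annotated genes made up 19.9 to 31.9% of uniquely aligned reads, ambiguous reads 3.21 to 4.67%, and 34875110 to 57872734 reads per library were tallied as not unique. Features without a symbol took 29.7 to 49.2% of gene counts, and the top 10 features 43.7 to 50.1%.

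The following choices were made before the data were examined: the groups, the tests, the gene lists, the rule for named genes, most of the alternatives, and the removal of libraries with under 100000 gene counts as failed. This rule removed 2 libraries, donor B DMSO 3 and donor C DMSO 2, whose counts were 0 in every gene. Their reads were tallied outside genes or as not unique, so whether the libraries or their counting failed is not known. The other libraries held 10034583 to 16894158 gene counts. A count of 0 in a library allows a level of up to 0.178 to 0.299 CPM, a count scaled to a common library size, taken as 3 counts of the library's total. Such limits cover the counting error of reads only. PCR copies are not independent molecules, so the limits may be too low. Replicate libraries were compared by a chi-square test over genes. The statistic per degree of freedom was 4.75 to 9.90 for 11 of the 14 pairs, 28.8 for donor B IA 2 against IA 3, and 122 and 107 for the pairs with donor B IA 1, so no library looked like a second copy of another.

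Counts were tested in R 4.3.3 with edgeR 4.0.16, by its quasi-likelihood F test after TMM scaling and filterByExpr on the 6 groups (minimum count 10, minimum total 15). In all, 13198 genes were tested. The comparison over all donors had donor as a covariate. The comparisons within a donor used a model of 6 group means over all 16 libraries, which shared 1 estimate of the spread. So did the test of whether the IA effect differed between donors (the interaction). IA replicates of donor B differed more than other replicates. The shared spread may therefore be too small for donor B and too large for donors A and C. The common biological coefficient of variation was 15.7%. Adjusted p is the Benjamini-Hochberg value over all genes tested, and 0.05 was the threshold. Log2 fold changes are IA against DMSO with their standard error (SE). Normalised levels are CPM on TMM-scaled library sizes. The counts "adjusted over the list alone" use the p-values of a list's own members.

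In all, 39 gene lists for this tissue and treatment, all with at least 5 tested members, were tested with camera of limma 3.58.1 at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera compares a list's genes with all others. Each list was also tested with an estimated correlation between its genes and with fry, which asks whether the list's genes move on balance in 1 direction. Over all donors the lists that held with an estimated correlation were NRF2 targets, AHR targets, chemokines, metallothioneins, monocyte markers, scavenger and pattern recognition receptors, tryptophan and kynurenine metabolism, and anti-inflammatory genes.

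Genes were named by a fixed rule. Over all donors it took the 10 largest rises and 10 largest falls past the threshold with a mean of at least 3 log2 CPM and the same sign in all 3 donors, plus 17 preset genes of inflammation, NRF2 and AHR. Within a donor it took up to 5 rises and 5 falls, for the interaction the 10 smallest p-values, and for a list up to 4 members with the smallest p-values. Genes known to be absent or silent in some people were never named per donor.

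The steps were tested on simulated counts with 200 changed genes in 3 sets per comparison. At 1.5-fold, 77.1% of changed genes were called over all donors, 27.4% in donor A, 14.4% in donor B and 13.9% in donor C. At 2-fold these shares were 98.0, 75.6, 69.7 and 63.2%. Of the genes called, 4.12, 7.37, 6.13 and 4.11% were false. In each comparison all 6 lists shifted by 1.3-fold were called and none of 60 unshifted lists was. Genes were simulated independently of each other, so these list counts do not cover lists of correlated genes. With the real counts, other splits of the libraries over all donors called a median of 6 lists and up to 17. The RNA concentration given in the labels was compared by an exact permutation test within donors. Alternatives were DESeq2 size factors, upper-quartile scaling, library totals without scaling factors, other filters, DESeq2 1.42.0, limma-voom, an adjusted p under 0.01, the replicate number as a block, RNA concentration as a covariate, no donor term, counts summed per donor, each donor's own libraries, and leaving out each library in turn. Those chosen after the data were seen were library totals, features with a symbol only, differences of lists between donors, and list tests without donor B IA 1. Figures and the remaining steps used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.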

Results

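PBMCs, the lymphocytes and monocytes of blood, were taken from 3 donors (A, B and C). They were treated for 45 min with 80 µM IA, an indole that gut bacteria make from tryptophan, or with 0.1% DMSO, and then stimulated for 20 h with 1 ng/mL LPS, a bacterial cell wall component that activates monocytes through CD14 and TLR4. Culture lasted 21 h in 0.5% human serum. The series title names an anti-inflammatory effect of IA, so each comparison asks which transcripts differed between IA and DMSO in LPS-stimulated cells. Unstimulated cells were not analysed here. Each donor had 3 DMSO and 3 IA libraries. In donor B DMSO 3 and donor C DMSO 2 every gene had a count of 0, which left 16 libraries (7 DMSO, 9 IA) of 10034583 to 16894158 gene counts, with 19185 to 21017 genes detected in each. Nothing in the labels says that replicates came from separate cultures, and within a donor all libraries are of 1 person, so p-values measure the spread between these samples, which may be technical. Per the labels, DMSO and IA libraries also lay in separate plate columns with separate index primers, and donors in separate plate rows. Treatment therefore cannot be separated from column and index, nor donor from row.

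Donors separated on the first 2 principal components, which held 27.7 and 21.9% of the variance. On the first component donor A lay at −34.0 to −29.9 and donor C at 34.9 to 41.5, and on the second donor B lay at −55.6 to −29.2. Donor B IA 1 stood apart from the other libraries. It correlated with its own group at 0.961, against 0.969 and 0.966 for donor B IA 2 and IA 3 and 0.975 to 0.980 for all libraries outside that group. Of its uniquely aligned reads 31.9% lay outside genes, against at most 26.3% in the other libraries, and features without a symbol took 49.2% of its gene counts.

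The RNA yield given in the labels was 46.9 ± 5.63 ng/µL with DMSO and 41.7 ± 7.56 ng/µL with IA (SD, n = 9 each). The mean was lower with IA in 3 of 3 donors, but the difference of −5.17 ng/µL was within the spread between samples (exact two-sided permutation test within donors, p = 0.141, 8000 arrangements). The largest gap was in donor B, from 49.1 ± 7.32 to 37.1 ± 8.59 ng/µL (SD, n = 3 each).

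Over all donors, the heme-degrading enzyme HMOX1 rose most with IA among the named genes, by 2.38 ± 0.16 on the log2 scale (SE; n = 7 DMSO and 9 IA; adjusted p = 8.36e-10). CYP1A1, a monooxygenase induced by the aryl hydrocarbon receptor (AHR), rose by 1.51 ± 0.17 (adjusted p = 6.54e-06). The LPS co-receptor CD14 fell by 1.08 ± 0.11 (adjusted p = 4.05e-06), the monocyte chemoattractant CCL2 fell by 1.06 ± 0.13 (adjusted p = 2.53e-05), and the zinc-binding protein MT2A fell by 0.87 ± 0.11 (adjusted p = 2.53e-05). The cytokine IL6 fell by 0.57 ± 0.09 (adjusted p = 0.000968), whereas TNF, at 0.08 ± 0.10 (adjusted p = 0.891), and IL1B, at −0.27 ± 0.14 (adjusted p = 0.664), did not pass. In all, 115 of 13198 genes changed, 42 of them upward and 73 downward. Of these, 12 rose and 6 fell by more than 2-fold, 4 had no symbol, and 114 had the same sign in all 3 donors. The genes were called on the same libraries, so the shared sign is not a separate test.

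Normalised levels, from the same counts, had the same directions within each donor. The naming rule required this of CD14 and CCL2, so it is no separate support. HMOX1 went from 46.2 ± 0.659 to 351 ± 38.7 CPM in donor A, from 18.8 ± 1.07 to 71.5 ± 18.3 CPM in donor B and from 9.78 ± 1.63 to 41.4 ± 15.2 CPM in donor C (SD; n = 3, except n = 2 for DMSO in donors B and C). CD14 went from 176 ± 2.66 to 80.6 ± 11.6 CPM in donor A, from 53.4 ± 4.44 to 28.2 ± 7.09 CPM in donor B and from 191 ± 78.5 to 84.9 ± 7.92 CPM in donor C. CCL2 went from 530 ± 83.3 to 309 ± 38.3, from 69.6 ± 11.6 to 24.5 ± 5.27 and from 1229 ± 461 to 622 ± 82.1 CPM in donors A, B and C. CYP1A1 was far less abundant, at 1.12 to 7.66 CPM with DMSO and 3.48 to 18.6 CPM with IA as donor means.

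**Figure D1:**
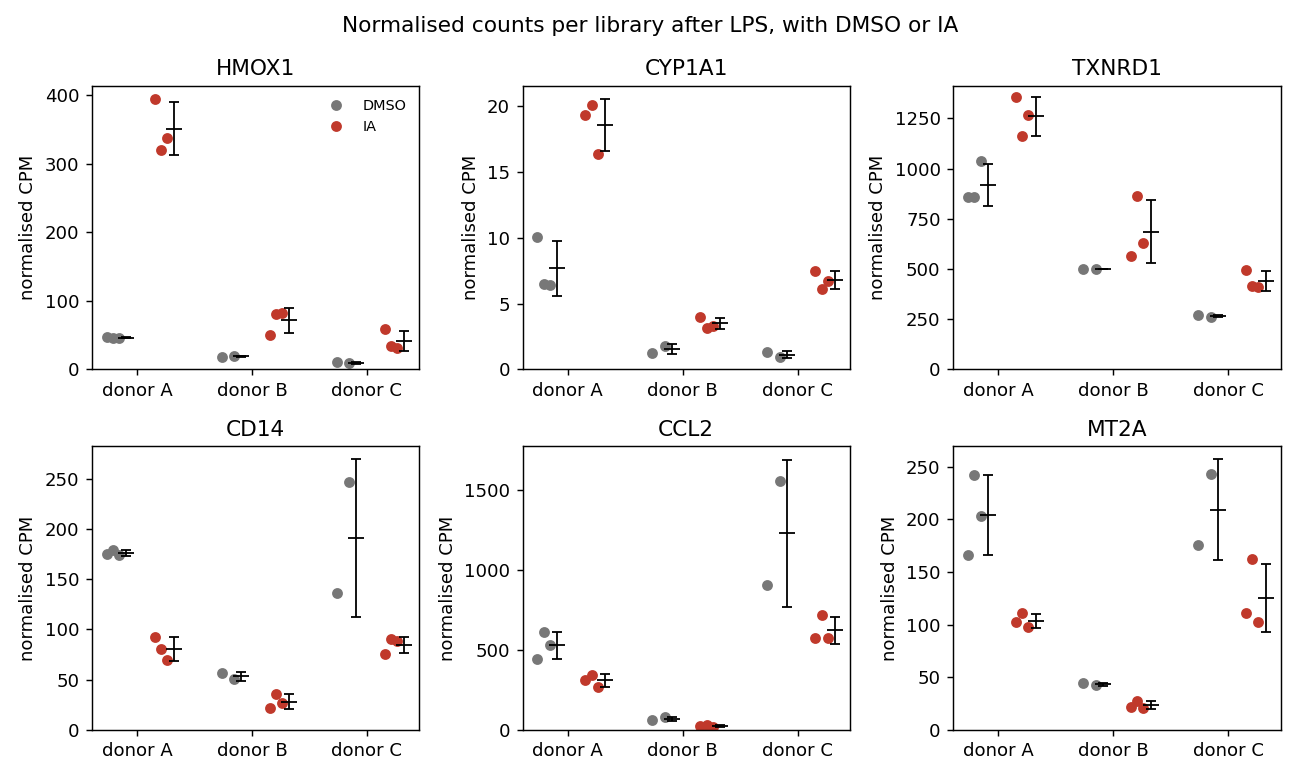
Normalised level (CPM, vertical axis) of HMOX1, CYP1A1, TXNRD1, CD14, CCL2 and MT2A in each of the 16 libraries (points) of donors A, B and C, DMSO in grey and IA in red, with bars for the group mean and SD. In donor A HMOX1 went from a mean of 46.2 to 351 CPM and CD14 from 176 to 80.6 CPM.

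Other named rises were PPIF, a regulator of the mitochondrial permeability pore (1.06 ± 0.17, adjusted p = 0.000821), TM4SF19 (0.86 ± 0.15, adjusted p = 0.00141), the protease inhibitor SPINK1 (0.83 ± 0.13, adjusted p = 0.000388) and the collagenase MMP1 (0.78 ± 0.16, adjusted p = 0.00976). AKIRIN1, ETS2, SNX20, PCSK5 and MICAL2 rose by 0.61 to 0.70. Among the named falls, the formyl peptide receptor FPR2 fell by 0.94 ± 0.12 (adjusted p = 3.45e-05), interferon gamma (IFNG) fell by 0.92 ± 0.17 (adjusted p = 0.00529) and the neutrophil chemoattractant CXCL1 fell by 0.78 ± 0.15 (adjusted p = 0.00526). C19orf59 and the chemokine CCL7 fell by 0.75 ± 0.13 (adjusted p = 0.0013) and by 0.72 ± 0.15 (adjusted p = 0.0135).

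Targets of NRF2, the transcription factor of the antioxidant response, rose as a list (median log2 change 0.16, camera adjusted p = 7.06e-11). Of its 28 tested members 4 rose, none fell and 24 did not pass, with 4 also called when adjusted over the list alone. The 4 were HMOX1, thioredoxin reductase TXNRD1 (0.54 ± 0.10, adjusted p = 0.00518), the quinone reductase NQO1 (0.45 ± 0.10, adjusted p = 0.0165) and AKR1C1 (0.64 ± 0.15, adjusted p = 0.0325). GCLM, which is also on the glutathione metabolism list, was at 0.21 ± 0.14 (adjusted p = 0.761) and SRXN1 at −0.15 ± 0.23 (adjusted p = 0.925). AHR targets rose as well (median 0.26, camera adjusted p = 1.92e-11). Of 12 tested members 3 rose and 9 did not pass, against 4 adjusted over the list alone. They were CYP1A1, TIPARP (0.49 ± 0.08, adjusted p = 0.00155) and NQO1, which is on both lists, while CYP1B1 (0.17 ± 0.19, adjusted p = 0.877) and the AHR repressor AHRR (0.15 ± 0.12, adjusted p = 0.821) did not pass.

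Chemokines fell as a list (median −0.41, camera adjusted p = 4.35e-20). Of 27 tested members 8 fell, none rose and 19 did not pass, against 14 falls adjusted over the list alone. Beside CCL2, CXCL1 and CCL7, CXCL5 fell by 0.71 ± 0.12 (adjusted p = 0.0013) and CCL20, which attracts lymphocytes and dendritic cells, fell by 0.58 ± 0.11 (adjusted p = 0.00639). The mean level of the chemokines lay below the donor's mean in all 9 IA libraries and above it in all 7 DMSO libraries. So did that of the monocyte markers (median −0.31). The donor's mean was the midpoint of its DMSO and IA group means. A list that fell in a donor therefore lay on these sides on average by construction, so this is no separate support. IL8, the neutrophil chemokine CXCL8, was at −0.17 ± 0.16 (adjusted p = 0.856). Pro-inflammatory cytokines fell (median −0.13, camera adjusted p = 0.00186; adjusted p = 0.342 with an estimated correlation). Of 26 tested members 3 fell and 23 did not pass, against 2 rises and 4 falls adjusted over the list alone. IL6, IFNG and the granulocyte growth factor CSF3 (−0.78 ± 0.17, adjusted p = 0.0229) were the 3, and the interleukin 12 subunit IL12B stood at −0.56 ± 0.16 (adjusted p = 0.147, and 0.0294 without donor C DMSO 3). The NF-kB response fell (31 tested, median −0.08, camera adjusted p = 0.000956; adjusted p = 0.104 with an estimated correlation). Of it, 4 members fell, against 7 adjusted over the list alone: BCL2A1, TNFAIP6, TNIP3 and the prostaglandin synthase PTGS2 (−0.48 ± 0.11, adjusted p = 0.0372). Its mean level lay below the donor's mean in 6 of 9 IA libraries. Anti-inflammatory and regulatory genes fell too (26 tested, median −0.09, camera adjusted p = 0.0118), with falls of the inhibitory receptor LILRB4 (−0.64 ± 0.11, adjusted p = 0.0013) and of the cytokine IL10 (−0.43 ± 0.10, adjusted p = 0.0335). These were 2 falls, against 3 adjusted over the list alone.

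Monocyte markers fell (median −0.31, camera adjusted p = 2.11e-16). Of 19 tested members 4 fell and 15 did not pass, against 8 falls adjusted over the list alone. CD14, MS4A7 (−0.60 ± 0.09, adjusted p = 0.000335), the formyl peptide receptor FPR1 (−0.58 ± 0.13, adjusted p = 0.022) and the calcium-binding protein S100A9 (−0.45 ± 0.11, adjusted p = 0.0341) were the 4. The mean level of the 19 markers lay below the donor's mean in all 9 IA libraries and above it in all 7 DMSO libraries. Whether the falls of other lists were separate from that of the monocyte markers was not tested. Among lymphocyte lists, T cell markers had a median of 0.08 (20 tested, camera adjusted p = 0.0996) and natural killer (NK) cell markers of −0.14 (19 tested, camera adjusted p = 0.0984). B cell markers fell (14 tested, median −0.16, camera adjusted p = 0.00571; adjusted p = 0.126 with an estimated correlation). Of these, 1 gene fell, the transcription factor SPIB (−0.61 ± 0.15, adjusted p = 0.0482), against 3 adjusted over the list alone.

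Scavenger and pattern recognition receptors fell (18 tested, median −0.13, camera adjusted p = 3.64e-06). CD14, the lectin CLEC4E (−0.80 ± 0.14, adjusted p = 0.00141) and the RNA sensor TLR8 (−0.91 ± 0.21, adjusted p = 0.0335) made up the 3 falls, also 3 adjusted over the list alone. CD14 is on the monocyte marker list as well, and without donor B IA 1 the median of the receptors was −0.20. Metallothioneins and zinc export genes, most of which bind zinc and copper, fell by the widest median of any list (11 tested, median −0.66, camera adjusted p = 2.53e-19). There were 5 falls, against 8 adjusted over the list alone, and MT1G fell by 1.29 ± 0.18 (adjusted p = 0.000194). Reads shared between these near-identical genes leave single members uncertain. Tryptophan and kynurenine metabolism fell (10 tested, median −0.18, camera adjusted p = 1.06e-06). As for the monocyte markers and the metallothioneins, its mean level lay below the donor's mean in all 9 IA libraries. It lay above that mean in all 7 DMSO libraries. Its 2 falls, against 3 adjusted over the list alone, were the tryptophan-degrading enzyme IDO1 (−0.75 ± 0.10, adjusted p = 7.55e-05) and the aromatic amino acid oxidase IL4I1 (−0.73 ± 0.12, adjusted p = 0.0012).

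Several further lists passed at the preset correlation and not with an estimated one. Reactive oxygen species production fell (8 tested, median −0.12, camera adjusted p = 0.000773; adjusted p = 0.0865 with an estimated correlation). Its 1 fall, also 1 adjusted over the list alone, was CYBB, the catalytic subunit of the phagocyte oxidase (−0.67 ± 0.09, adjusted p = 3.41e-05). Macrophage maturation genes fell (17 tested, median −0.24, camera adjusted p = 0.00788; adjusted p = 0.126 with an estimated correlation), with 2 falls, CHI3L1 (−0.71 ± 0.12, adjusted p = 0.00221) and osteopontin (SPP1; −0.43 ± 0.10, adjusted p = 0.0452), against 3 adjusted over the list alone. Platelet markers fell (8 tested, median −0.15, camera adjusted p = 0.0452; adjusted p = 0.169 with an estimated correlation), with 1 fall, PPBP (−0.42 ± 0.09, adjusted p = 0.0229), against 2 adjusted over the list alone. Antigen presentation by MHC class II (15 tested, median −0.18, camera adjusted p = 0.000956; adjusted p = 0.104 with an estimated correlation) and the inflammasome (16 tested, camera adjusted p = 0.00403; adjusted p = 0.0865 with an estimated correlation) fell with no member called. Adjusted over the list alone, 2 and 1 of their members fell. The monocyte markers (median −0.31) fell in the same libraries, and whether the falls above are separate from theirs was not tested. Glycolysis and hypoxia genes (29 tested, median −0.10, camera adjusted p = 0.0139; adjusted p = 0.434 with an estimated correlation) and cytosolic ribosomal proteins (50 tested, median −0.09, camera adjusted p = 0.000773; adjusted p = 0.677 with an estimated correlation) fell with 0 members called either way. Donor B IA 1, the library that stood apart, had the lowest ribosomal protein level.

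Cholesterol synthesis and uptake (23 tested, median 0.10, camera adjusted p = 0.0492; adjusted p = 0.413 with an estimated correlation), p53 and apoptosis genes (19 tested, median 0.07, camera adjusted p = 0.0492; adjusted p = 0.104 with an estimated correlation) and nuclear-retained RNAs (6 tested, camera adjusted p = 0.0462; adjusted p = 0.104 with an estimated correlation) rose with 0 members called by edgeR. Adjusted over the list alone, 2 members of the list named nuclear-retained RNAs rose, a name that may not hold for each member. None of the members of the cholesterol and p53 lists passed.

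The remaining lists did not pass. Interferon-stimulated genes had a median of −0.16 (38 tested, 30 lower and 8 higher, camera adjusted p = 0.112), the ATF4 and unfolded protein response 0.07 (24 tested, camera adjusted p = 0.0571), the heat shock response 0.03 (adjusted p = 0.184) and nuclear-encoded oxidative phosphorylation −0.05 (adjusted p = 0.176). T cell activation genes (adjusted p = 0.188) held 1 fall, IFNG, also 1 adjusted over the list alone, and eicosanoid synthesis and receptors (adjusted p = 0.236) 1 fall, PTGS2, against 1 rise and 2 falls adjusted over the list alone. Glutathione metabolism (camera adjusted p = 1.00) held 1 rise, also 1 adjusted over the list alone, of the transferase MGST1 (0.49 ± 0.09, adjusted p = 0.00578). Matrix remodelling (camera adjusted p = 1.00) held a rise of MMP1 and falls of the metalloproteinases MMP7 (−0.62 ± 0.13, adjusted p = 0.0105) and MMP9 (−0.43 ± 0.10, adjusted p = 0.0443), against 2 rises and 2 falls adjusted over the list alone. Camera adjusted p-values were 0.318 for mitochondrially encoded mRNAs, 0.536 for dendritic cell and for erythroid markers, 0.693 for immediate early genes and for the proteasome, 0.744 for neutrophil markers, and 1.00 for the cell cycle and for LXR targets and lipid efflux. None of those 8 lists held a called gene. Leaving out 1 library let some of these lists pass at the preset correlation, with none of those 20 calls passing with an estimated correlation (adjusted p = 0.124 to 0.800). Without donor B IA 1 the heat shock response (adjusted p = 0.0108), T cell markers (0.0225) and the ATF4 response (0.00298) rose, the last also without donor B DMSO 1, DMSO 2 or IA 2 (0.0108, 0.0244 and 0.0363). NK cell markers fell without donor A DMSO 2, DMSO 3 or IA 2 (0.0473, 0.0280 and 0.0266), oxidative phosphorylation fell without donor C DMSO 1 (0.0172) and mitochondrially encoded mRNAs rose without donor B IA 3 (0.0134). Interferon-stimulated genes rose without donor A DMSO 2 (0.00237), and fell without donor C IA 2 (1.24e-06) and without donor A DMSO 1 or DMSO 3, donor B DMSO 1, DMSO 2 or IA 2, or donor C DMSO 1 or DMSO 3 (0.00342 to 0.0408).

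In total 21 of 39 lists passed over all donors, 5 upward and 16 downward, and 8 passed with an estimated correlation. Leaving out 1 library moved the count of changed genes to 71 (without donor B DMSO 1), 73 (without donor A IA 3) and 190 (without donor B IA 1). Of the 27 called named genes 20 were called whichever library was left out, and the others were AKIRIN1, ETS2, CCL7, NQO1, MICAL2, IL10 and PTGS2, with highest adjusted p of 0.0691, 0.0569, 0.0730, 0.0642, 0.152, 0.126 and 0.151. The ribosomal protein call was lost without donor B DMSO 2 (adjusted p = 0.128) or donor B IA 1 (adjusted p = 0.170), that of glycolysis and hypoxia without donor B DMSO 1 (adjusted p = 0.0959) or donor B IA 1 (adjusted p = 0.0881), and that of anti-inflammatory genes without donor C DMSO 3 (adjusted p = 0.0506), while the platelet, cholesterol, p53 and nuclear-retained calls were lost in 12, 10, 11 and 8 of 16 such fits. Without 1 library the medians of some called lists moved by over 1.5 times: pro-inflammatory cytokines to −0.04 (donor B DMSO 2) and −0.20 (donor C DMSO 1), the NF-kB response to −0.05 and the inflammasome from −0.15 to −0.10 (donor A IA 2), anti-inflammatory genes to −0.15 (donor A DMSO 1) and −0.06 (donor A DMSO 3), glycolysis to −0.03 (donor B IA 1), ribosomal proteins to −0.03 (donor B IA 1) and −0.04 (donor B DMSO 2), p53 genes to 0.05, 0.04 and 0.03 (donor A DMSO 2, donor C DMSO 1 and DMSO 3), and platelet markers to −0.25, −0.03, −0.06, −0.06 and −0.09 (donor A IA 1, IA 2, donor C DMSO 1, DMSO 3 and IA 3) or, with the sign turned, 0.03 (donor B DMSO 1). With counts summed per donor, so that the donor is the replicate, 8 of the 27 named genes lost their call: TIPARP (adjusted p = 0.0515), MMP1 (0.0539), CXCL1 (0.0610), MICAL2 (0.0646), TXNRD1 (0.0861), NQO1 (0.181), IL10 (0.186) and PTGS2 (0.195), as did the anti-inflammatory, platelet, p53 and cholesterol lists (0.0503, 0.0761, 0.0836 and 0.113), and without a donor term all 27 did. IL10 also lost its call by limma-voom (0.0506), with library totals (0.0604) and with RNA concentration as a covariate (0.0623), the last also ending that of MICAL2 (0.142).

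**Figure D2:**
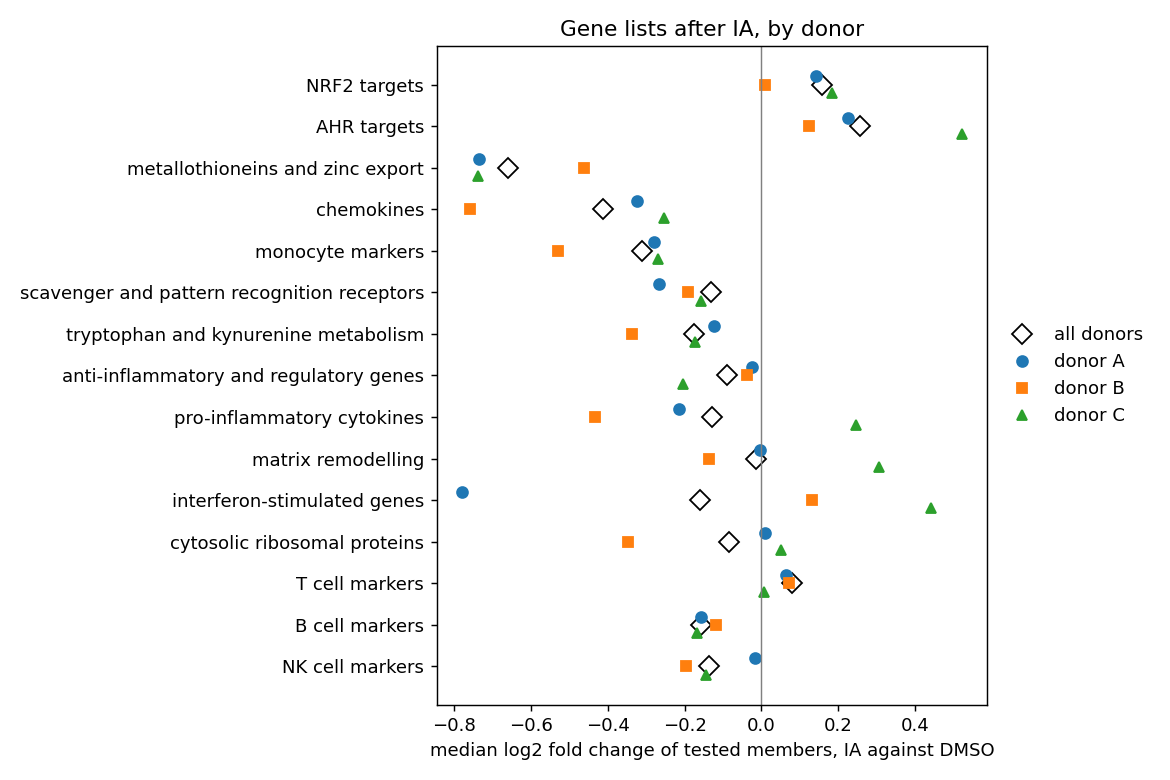
Median log2 fold change (IA against DMSO, horizontal axis) of the tested members of 15 gene lists, for all donors together (diamonds) and for donors A, B and C. The medians over all donors ran from −0.66 for metallothioneins to 0.26 for AHR targets, and monocyte markers lay at −0.28, −0.53 and −0.27 in donors A, B and C.

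In donor A (3 DMSO and 3 IA libraries), HMOX1 rose by 2.93 ± 0.21 (SE, adjusted p = 8.32e-09) and CYP1A1 rose by 1.27 ± 0.18 (adjusted p = 0.000734). MMP1 rose by 1.31 ± 0.20 (adjusted p = 0.00177), TM4SF19 by 1.24 ± 0.17 (adjusted p = 0.000527), the transcription factor CREBZF by 1.18 ± 0.22 (adjusted p = 0.0117) and SPINK1 by 1.09 ± 0.17 (adjusted p = 0.00179). IFNG fell by 1.69 ± 0.30 (adjusted p = 0.00993), CHI3L1, a glycoprotein secreted by macrophages, fell by 1.15 ± 0.13 (adjusted p = 4.89e-05), and CD14 fell by 1.13 ± 0.18 (adjusted p = 0.00391). In all 14 genes rose and 11 fell.

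NRF2 targets rose in donor A (median 0.14, camera adjusted p = 8.39e-10), with 1 of 28 members called and 6 rises adjusted over the list alone. AHR targets rose (median 0.23, camera adjusted p = 1.25e-06; adjusted p = 0.0547 with an estimated correlation), with 1 of 12 called and 3 adjusted over the list alone. Metallothioneins fell (median −0.74, camera adjusted p = 2.12e-12), with 1 fall, MT2A, and 6 adjusted over the list alone. Monocyte markers fell (median −0.28, camera adjusted p = 2.55e-07), with falls of CD14 and MS4A7, also 2 adjusted over the list alone. Chemokines (median −0.32, camera adjusted p = 2.03e-07; adjusted p = 0.101 with an estimated correlation) and pro-inflammatory cytokines (median −0.21, camera adjusted p = 8.54e-06; adjusted p = 0.103 with an estimated correlation) fell, each with 1 fall, CXCL5 (−0.91 ± 0.18, adjusted p = 0.0323) and IFNG, against 5 falls each adjusted over the list alone. Interferon-stimulated genes fell (median −0.78, 38 of 38 lower, camera adjusted p = 9.22e-14; adjusted p = 0.246 with an estimated correlation) with 0 members called by edgeR and 4 falls adjusted over the list alone. In donor A DMSO 2 their mean level was 1.56 above the donor's mean on the log2 scale, and without that library the list did not pass and its direction turned (median 0.05, camera adjusted p = 0.820). The AHR median was 0.15 without donor A DMSO 1 and 0.34 without DMSO 3, and that of chemokines −0.21 without IA 3.

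Altogether 17 lists passed in donor A, and 3 of them with an estimated correlation. Without donor A DMSO 1, DMSO 2, IA 1, IA 2 or IA 3 the count of changed genes went from 25 to 14, 11, 16, 13 or 10, and without donor B IA 1 to 56. Of the 10 called named genes HMOX1, MMP1, TM4SF19, SPINK1 and CHI3L1 were called in every such fit. CREBZF lost its call without donor A DMSO 1, DMSO 3, IA 1 or IA 3 (highest adjusted p = 0.158), IFNG without DMSO 2, IA 1 or IA 3 (0.133) and by limma-voom (0.0882), CD14 without IA 3 (0.0831), MT2A without DMSO 2 or any IA library (0.127) and FPR2 without any donor A library or donor C IA 1 (0.356).

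In donor B (2 DMSO and 3 IA libraries), HMOX1 rose by 1.93 ± 0.24 (SE, adjusted p = 0.000428) and SNX20, a sorting nexin, by 1.09 ± 0.19 (adjusted p = 0.0166). HPCAL1 and ZC3H7A rose by 1.24 ± 0.26 (adjusted p = 0.0434) and by 1.16 ± 0.23 (adjusted p = 0.0298). The hyaluronan synthase HAS1 fell by 1.87 ± 0.29 (adjusted p = 0.00543), CCL2 fell by 1.503 ± 0.22 (adjusted p = 0.00288), the kinase MATK fell by 1.40 ± 0.22 (adjusted p = 0.00571), CXCL1 fell by 1.26 ± 0.23 (adjusted p = 0.0227) and CCL20 fell by 0.95 ± 0.18 (adjusted p = 0.0241). In all 5 genes rose and 17 fell. These SE and p-values use the spread shared with the other donors, whose replicate libraries differed less than the IA libraries of donor B.

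Chemokines fell in donor B (median −0.76, camera adjusted p = 4.66e-19), with 4 falls, CCL2, CXCL1, CCL20 and PPBP, against 17 adjusted over the list alone. Monocyte markers fell (median −0.53, camera adjusted p = 6.66e-08) with 0 members called and 7 falls adjusted over the list alone, and CD14 stood at −0.92 ± 0.21 (adjusted p = 0.0585). Macrophage maturation genes fell (median −0.45, camera adjusted p = 7.55e-05), with falls of SPP1 (−0.87 ± 0.14, adjusted p = 0.00676) and CHI3L1, 2 in all, against 5 adjusted over the list alone. Reactive oxygen species production fell (median −0.37, camera adjusted p = 0.000186), with 1 fall, CYBB (−0.79 ± 0.15, adjusted p = 0.0298), against 3 adjusted over the list alone. Pro-inflammatory cytokines fell (median −0.43, camera adjusted p = 2.46e-06; adjusted p = 0.0972 with an estimated correlation), with 1 fall, IL6 (−0.81 ± 0.16, adjusted p = 0.0298), against 6 adjusted over the list alone. Cytosolic ribosomal proteins fell (median −0.35, 50 of 50 lower, camera adjusted p = 5.34e-18; adjusted p = 0.228 with an estimated correlation) with 0 members called either way. Donor B IA 1 had the lowest level of them, and without it the median was −0.18. NRF2 targets (median 0.01, camera adjusted p = 0.0970) and AHR targets (median 0.12, camera adjusted p = 0.169) did not pass, although without donor B IA 1 both rose at the preset correlation (medians 0.12 and 0.27, camera adjusted p = 0.000263 and 0.00188; adjusted p = 0.107 and 0.0861 with an estimated correlation).

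All 17 lists that passed in donor B fell, and 4 passed with an estimated correlation. The median of pro-inflammatory cytokines was −0.27 without donor B DMSO 2, and that of macrophage maturation genes −0.23, −0.74 and −0.20 without DMSO 2, IA 2 and IA 3. Without donor B DMSO 1, DMSO 2, IA 1, IA 2 or IA 3 the count of changed genes went from 22 to 3, 6, 34, 124 or 271, and without donor C DMSO 3 to 42. HMOX1 alone among the 9 called named genes was called in every such fit. The calls of HAS1, MATK and SNX20 were lost without donor B DMSO 1 (adjusted p = 0.195, 0.195 and 0.464), that of CCL2 without donor B DMSO 2 (0.0635), those of CXCL1 and CCL20 without either (highest 0.226 and 0.212), that of ZC3H7A without either or donor B IA 1 (highest 0.568), and that of HPCAL1 without either, any donor A library or donor C IA 3 (highest 0.523). Fitted on donor B's libraries alone, 6 of the 9 lost their call, namely SNX20 (0.225), HPCAL1 (0.0645), ZC3H7A (0.322), MATK (0.152), CXCL1 (0.645) and CCL20 (0.625), and HPCAL1 also with DESeq2 size factors (0.0527) or RNA concentration as a covariate (0.0766).

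In donor C (2 DMSO and 3 IA libraries), HMOX1 rose by 2.08 ± 0.25 (SE, adjusted p = 0.000163) and CYP1A1 rose by 2.58 ± 0.30 (adjusted p = 0.000126). The growth factor epiregulin (EREG) rose by 1.37 ± 0.22 (adjusted p = 0.00315), the chemokine CCL1 by 1.29 ± 0.18 (adjusted p = 0.000733), the myeloid growth factor CSF2 by 1.23 ± 0.17 (adjusted p = 0.000733) and tissue factor (F3), which starts coagulation, by 0.74 ± 0.15 (adjusted p = 0.0436). CD14 fell by 1.17 ± 0.20 (adjusted p = 0.00923) and the inhibitory receptor LAIR1 fell by 1.08 ± 0.19 (adjusted p = 0.00923). In all 9 genes rose and 3 fell.

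AHR targets rose in donor C (median 0.52, camera adjusted p = 4.25e-15), with rises of CYP1A1 and EREG, 2 in all, against 5 adjusted over the list alone. NRF2 targets rose (median 0.18, camera adjusted p = 4.55e-07), with 1 rise, HMOX1, against 3 adjusted over the list alone. Metallothioneins fell (median −0.74, camera adjusted p = 2.46e-12) with 0 members called and 7 falls adjusted over the list alone. Monocyte markers fell (median −0.27, camera adjusted p = 2.53e-05), with 1 fall, CD14, against 4 adjusted over the list alone. Pro-inflammatory cytokines rose (median 0.25, camera adjusted p = 4.48e-05; adjusted p = 0.150 with an estimated correlation), with 1 rise, CSF2, against 7 rises and 3 falls adjusted over the list alone. Chemokines fell (median −0.25, camera adjusted p = 0.00104; adjusted p = 0.270 with an estimated correlation), although CCL1 rose and CCL8 fell, against 1 rise and 4 falls adjusted over the list alone. Interferon-stimulated genes rose (median 0.44, 38 of 38 higher, camera adjusted p = 0.000149; adjusted p = 0.619 with an estimated correlation) with 0 members called either way. In donor C IA 2 their mean level was 1.25 above the donor's mean on the log2 scale, and without that library the list did not pass and its direction turned (median −0.23, camera adjusted p = 0.108). Their median was 0.29 without donor C DMSO 1 and 0.73 without IA 3. Without donor C DMSO 3 the medians of monocyte markers, chemokines and NRF2 targets were −0.10, −0.09 and 0.29, and those of chemokines without IA 1 and NRF2 targets without DMSO 1 were −0.16 and 0.12.

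Of the 39 lists 16 passed in donor C, 9 upward and 7 downward, and 4 passed with an estimated correlation. The count of changed genes went from 12 to 7 without donor C DMSO 3 or IA 1 and to 30 without donor B IA 1. HMOX1 alone among the 7 called named genes was called in every fit that left out 1 library. Calls were lost without donor C DMSO 3 for EREG (also without DMSO 1; highest adjusted p = 0.113), CCL1 (0.1000), CSF2 (0.0719), CD14 (also without IA 1 or IA 3; 0.832) and LAIR1 (also without IA 1; 0.387), and F3 lost its call in 13 of 16 such fits (highest 0.832) and with RNA concentration as a covariate (0.0652).

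**Figure D3:**
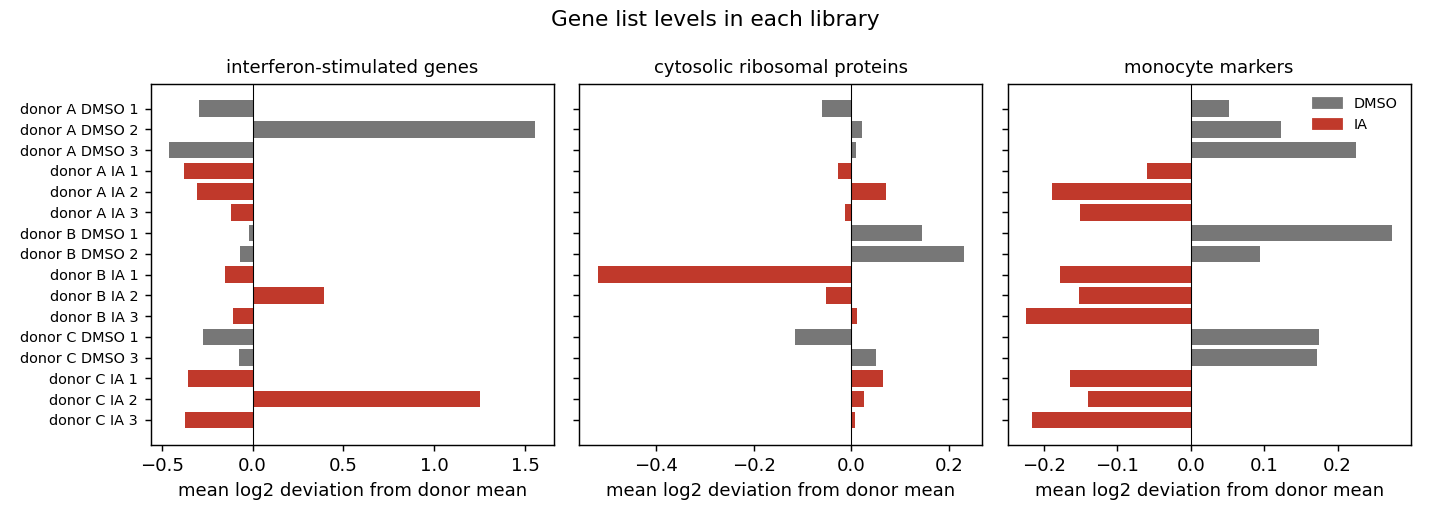
Mean level of interferon-stimulated genes, cytosolic ribosomal proteins and monocyte markers in each of the 16 libraries, as the log2 deviation from the donor's mean (horizontal axis, with bars for DMSO in grey and IA in red). Interferon-stimulated genes stood at 1.56 in donor A DMSO 2 and 1.25 in donor C IA 2, and monocyte markers lay below 0 in all 9 IA libraries.

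No gene passed edgeR's interaction test for a difference of the IA effect between donors (0 genes, with 876 at an unadjusted p under 0.05). DESeq2 called 11 and limma-voom 2, and edgeR without the low-count filter called 111. The genes nearest to the threshold were CCL1, with log2 changes of 0.02, −0.07 and 1.29 in donors A, B and C, and CSF2, with −0.21 in donor B and 1.23 in donor C (adjusted p = 0.0989 for each). CSF2 stood at 23.4 ± 1.34 CPM with DMSO and 55.0 ± 5.03 CPM with IA in donor C (SD, n = 2 and 3), and at 116 ± 23 and 147 ± 9.72 CPM in donor A (n = 3 each). F3 (adjusted p = 0.300), CHI3L1 (0.300), IL19 and HCAR2 (0.349 each), CCL24 (0.387), RALGAPB and C20orf123 (0.528 each) and IL36G (0.546) followed. Leaving out 1 library gave 1 gene without donor A DMSO 1 or donor C DMSO 3, 3 without donor B IA 2 and 5 without donor B IA 1 or IA 3. On simulated counts with 200 genes changed in 1 donor, the test called 95.2 genes on average, 88.4 of them among the 200. Genes shifted by 1.3-fold for the list test were not counted among the 200.

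Over all 13198 genes the log2 changes of donor A were weakly related to those of the other donors, and those of B and C were close to unrelated. Across genes, which are not independent replicates, Spearman's rho was 0.07 for donors A and B, 0.08 for A and C and −0.01 for B and C. Over the 5430 genes with a mean of at least 3 log2 CPM it was 0.14, 0.17 and −0.00. HMOX1 was called in all 3 donors. CHI3L1, LILRB1 and LRRC25 fell in both A and B, and CYP1A1, HS3ST2 and NMB rose and CD14 fell in both A and C; of these LILRB1, LRRC25, HS3ST2 and NMB are named only because they make up the overlap. The donors share no library, and independent lists would overlap by under 0.02 genes in each direction for every pair of donors. Of the 25 genes called in donor A, 25 had the same sign in donor B and 24 in donor C. The 22 of donor B had the same sign in 20 cases in donor A and 20 in donor C, and the 12 of donor C in 11 cases in A and 9 in B.

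As lists, pro-inflammatory cytokines differed between donors B and C (median difference in log2 change −0.64, B minus C, camera adjusted p = 8.89e-12; adjusted p = 0.0499 with an estimated correlation). They fell in donor B and rose in donor C at the preset correlation (adjusted p = 0.0972 and 0.150 with an estimated correlation). Matrix remodelling genes differed likewise (median difference −0.40, camera adjusted p = 2.06e-06; adjusted p = 0.0499 with an estimated correlation). At the preset correlation 12, 5 and 11 lists differed between A and B, A and C, and B and C, and with an estimated correlation 0, 0 and 2 did. The last count was 0 with DESeq2 size factors and in 13 of the 16 fits that left out 1 library, 1 without the low-count filter, 4 without donor B IA 2, and 2 without donor A IA 1 or IA 3 and with symbol features only. Without donor A IA 1, donor B IA 1 or donor C IA 3, 1 list differed between A and C with an estimated correlation. At the preset correlation, leaving out 1 library gave 7 to 15, 4 to 8 and 8 to 16 lists, with 7 between A and B without donor A DMSO 2 and 8 between A and C without donor B IA 1 or donor C DMSO 3, and 11 differed between A and C without the low-count filter.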

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

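All tests of explanations in this part were chosen after the result was seen, except the counts over other splits of the samples. Pro-inflammatory cytokines changed differently after IA in donors B and C, by a median of −0.64 in log2 fold change (B minus C), by a test of the difference itself. At the preset correlation this difference did not depend on 1 library, since the highest adjusted p over 16 fits that each left out 1 library was 3.09e-08. That is a weak check, since other splits of the libraries over all donors called a median of 6 lists at this correlation. Correlated genes within the list remain open: with an estimated correlation the adjusted p was 0.0499, was under 0.05 in 3 of those 16 fits, and ranged from 0.0321 to 0.159. A different response of the donors is a possible explanation, but donor and plate row cannot be told apart, and each of these donors kept only 2 DMSO libraries. Matrix remodelling genes differed between the same donors by a median of −0.40 at the preset correlation (adjusted p = 2.06e-06), with an adjusted p of 0.0499 with an estimated correlation and of 0.0568 without donor B IA 1.

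Monocyte markers fell after IA in all 3 donors, with a highest camera adjusted p of 2.53e-05 among them at the preset correlation. This argues against 1 donor carrying the fall. In donor C, however, the median moved from −0.27 to −0.10 without donor C DMSO 3, a fit with 1 DMSO library left in that donor. Whether a smaller share of monocytes is the whole cause of the fall of CD14 stays open: the 18 other tested markers had a median with a 95% bootstrap interval over genes of −0.47 to −0.18, against −0.86 for CD14 plus 2 SE, but CD14 was singled out as the marker that fell most, so this comparison decides nothing. Fewer monocytes among otherwise unaltered cells were taken to move the T, B and NK cell markers alike. Their medians were 0.08, −0.16 and −0.14 (permutation p = 0.0170, 100000 permutations of genes over the lists). The permutation treats genes as independent, while markers of 1 cell type may move together. Its p may therefore be too small and decides nothing. The condition that the other cells stay as they were was also added after this p was seen. A loss of monocytes, alone or together with another change of the cells, stays open. A lower expression of these genes per monocyte may also contribute, and plate column and index primers, which followed treatment, cannot be told apart from it.

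Donor B IA 1 stood apart, with a correlation of 0.961 with its group. Shallow sequencing is argued against by a library of another group with fewer counts, which correlated with its own group at 0.975. Reads from outside genes, perhaps from genomic DNA or unspliced RNA, stay open: they made up 31.9% of its uniquely aligned reads, above the highest other library at 26.3%, but the ribosomal protein fall in donor B was called without that library too (camera adjusted p = 3.02e-11). An effect of IA in donor B stays open as well: without that library the ribosomal median was −0.18, against −0.35 with it, which met the share asked for, but the list did not pass with an estimated correlation (adjusted p = 0.226), a condition added after the values were seen.

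For the count of changed genes over all donors, a random labelling of these libraries within donors is argued against. The splits cannot exclude a difference between cultures or plate columns. Replicates may be of 1 culture, and treatment followed column and index. The real split of the libraries within donors gave 115 genes, the highest other split 33, and 1 of 100 splits, the real one, gave as many. For gene lists the real split gave 21 and the highest other 17, again with 1 of 100 as large, although the other splits called a median of 6 lists at the preset correlation, so single lists that pass only there are weak. In donor A the 10 possible splits are too few for a share under 0.05. There the real split gave 25 genes and 17 lists, and the highest others gave 0 and 8.

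The 2 libraries in which every gene had a count of 0 still held reads tallied outside genes, 9342292 in donor B DMSO 3 and 8664659 in donor C DMSO 2. A further 20799288 and 17874094 were tallied as not unique. All of their uniquely aligned reads were tallied outside genes, against at most 31.9% in the other libraries. Whether the libraries or their counting failed was not tested.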

How the results depend on the processing

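Chosen after the data were seen were the tests with library totals, with symbol features only, of list differences between donors, and of lists without donor B IA 1. Counts of changed genes over all donors, in A, B and C and for the interaction were 115, 25, 22, 12 and 0. Leaving out 1 library gave 71 to 190, 10 to 56, 3 to 271, 7 to 30 and 0 to 5. Where 1 DMSO library was left in B or C, it was assumed to vary like the other groups. Without the low-count filter the counts were 222 (113 up, 109 down, 111 shared), 105, 211, 49 and 111. DESeq2 gave 39, 117, 28 and 11 in A, B, C and the interaction, and limma-voom 40 in B and 2 in the interaction. An adjusted p under 0.01 gave 54 over all donors, 14 in A and 6 in B. RNA concentration as a covariate gave 35 in B. No donor term gave 0 over all donors by edgeR (467 at an unadjusted p under 0.05; not run with other tools), and counts summed per donor gave 58. Each donor's own libraries, with their own spread instead of the shared one, gave 78, 3 and 43. Remaining settings gave 86 to 164, 23 to 33, 20 to 26 and 9 to 16. The cause was not tested, except that the stricter threshold calls fewer genes and summing leaves fewer samples. Same-numbered libraries did not deviate together (correlations of −0.040 to 0.047 in 7 pairs, against −0.056 to 0.056 in 14 others), so the numbers were not taken as pairs. In donors B and C, with 2 DMSO libraries each, these correlations mirror each other by construction, which weakens the check. In the labels, replicate 2 had the lowest RNA concentration in every group except donor A DMSO, and an effect of the replicate number on it was not tested. With the replicate block the counts were 65 over all donors and 60 in B, the calls of MMP1, IL10, PTGS2 and NQO1 over all donors (adjusted p = 0.0826, 0.0800, 0.130 and 0.125), FPR2 in A (0.0909) and LAIR1 and F3 in C (0.0745 and 0.158) were lost, as were those of the anti-inflammatory, cholesterol, p53, platelet and nuclear-retained lists over all donors (0.0613 to 0.0996), scavenger receptors in B (0.0557) and MHC class II, anti-inflammatory, p53 and macrophage maturation lists in C (0.0653 to 0.113), mitochondrially encoded mRNAs rose over all donors and in B (0.00608 and 0.0127) and the ATF4 response fell in B (0.0359), and interferon-stimulated genes in C turned (camera adjusted p = 0.0569, downward), while over all donors they fell (2.63e-06). They also turned without donor A DMSO 2 over all donors (0.00237) and in A (0.820), and without donor C IA 2 in C (0.108). Without 1 library their adjusted p ranged from 1.24e-06 to 0.511 over all donors, 6.60e-32 to 0.820 in A and 2.26e-10 to 0.108 in C. Lists, 21, 17, 17 and 16, fell to 8, 3, 4 and 4 with an estimated correlation and in A and C to 3 and 5 with fry, and leaving out 1 library gave 18 to 22, 13 to 18, 15 to 18 and 11 to 17. Of 976 leave-one-out values of named genes 872 kept their direction and side of the threshold, 103 lost and 1 gained a call. Of 714 under other settings 657 kept them, 56 lost and 1 gained. Every list called over all donors kept its median's sign under DESeq2 size factors, upper-quartile scaling and library totals. Library totals moved the median of all genes in B by 0.12 and gave 46 rises and 60 falls over all donors. Spearman correlations between donors stayed at 0.03 to 0.12, 0.04 to 0.10 and −0.03 to 0.04 without 1 library, and the RNA difference at −6.57 to −3.50 ng/µL. On the log2 scale it was −0.18. A depth minimum relative to the median removes only the 2 libraries already left out, so it gave no value of its own. In single donors simulated 1.5-fold changes were called in 13.9 to 27.4% of genes and 2-fold changes in 63.2 to 75.6%. Depth was not varied, and it allows up to 0.299 CPM behind a count of 0.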

Other observations

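The genes in this part were chosen after their values were seen, and no tests beyond those of all genes were run on them. Among genes that changed over all donors (7 DMSO and 9 IA libraries) and stand on no list here, several falls were picked out singly, without a test of any theme. The monocyte markers (median −0.31) fell in the same libraries. The Fc receptor gamma chain FCER1G fell by 0.54 ± 0.10 on the log2 scale (SE, adjusted p = 0.00518) and the kinase SYK, which acts downstream of it, fell by 0.39 ± 0.08 (adjusted p = 0.0191). The platelet-activating factor receptor PTAFR fell by 0.42 ± 0.08 (adjusted p = 0.00518), the inhibitory receptor LILRB1 fell by 0.74 ± 0.12 (adjusted p = 0.00113) and LRRC25 fell by 0.71 ± 0.08 (adjusted p = 1.4e-05). IRG1 (now ACOD1), the enzyme that makes itaconate in activated macrophages, fell by 1.36 ± 0.25 (adjusted p = 0.00524).

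Rises outside the lists included the lipid-sensing nuclear receptor PPARG (0.92 ± 0.17, adjusted p = 0.00359) and the fatty acid binding protein FABP3 (1.15 ± 0.26, adjusted p = 0.0289). The small GTPase GEM rose by 1.20 ± 0.15 (adjusted p = 3.01e-05), the neuropeptide gene NMB by 1.27 ± 0.15 (adjusted p = 2.53e-05) and the autophagy gene GABARAPL1 by 0.46 ± 0.09 (adjusted p = 0.00574). FTLP2, a pseudogene of ferritin light chain whose reads cannot be separated from those of FTL, rose by 0.56 ± 0.11 (adjusted p = 0.00958), while FTL itself, which is on the NRF2 list, stood at 0.32 ± 0.15 (adjusted p = 0.525).

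Interferon-stimulated genes stood well above the donor's mean in 2 libraries. The mean of 38 such genes was 1.56 above the donor's mean on the log2 scale in donor A DMSO 2 (2.94-fold) and 1.25 above it in donor C IA 2 (2.38-fold). In the other 14 libraries it lay between −0.46 and 0.40.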
